A study of Mus musculus with 137 samples.

How the data were processed

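The data were gene-level read counts deposited by the authors for 137 lungs of male C57BL/6J mice, and the unit was called counts per the labels. The file held 48794 genes by Ensembl identifier, all values were whole numbers, and 36251 genes had at least 1 read. Per the labels, RNA was taken with Qiazol from 20 mg of flash-frozen tissue, libraries were built with a poly-A kit, and reads passed through bcl2fastq 2.20.0.422, STAR 2.5.2 or 2.5.2b and featureCounts 1.5.1. RSEM 1.3.0 and FastQC 0.11.5 were named as well, with 3 builds (hg38, GRCh38 and GRCm38) whose roles were not given in the sources used here. The strand setting, the annotation release and the rule for multi-mapping reads were not given in the sources used here either. No raw reads were used here.

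Gene symbols, biotypes and GRCm38 positions came from GENCODE M21, which named 48434 of the genes in the file and 18348 of the genes tested. Among the tested genes 8 symbols occurred more than once and were kept apart by identifier. The protein measurements of the series were not used here.

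Groups were the 26 combinations of age, treatment and day in the labels, with 4 to 11 lungs each, and every lung was 1 library. Genes were kept when edgeR filterByExpr passed them with a minimum count of 10 and a minimum total of 15, which left 18396 genes. Library sizes were scaled by TMM. The test was the edgeR quasi-likelihood F test (glmQLFit and glmQLFTest, robust) on all 137 libraries with 1 coefficient per group and 111 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. Fold changes are those of glmQLFTest at its default settings, and the ± values beside them are standard errors. These were computed as the absolute log2 fold change divided by the square root of F. They rest on a gene's spread over all 137 libraries and do not measure that of the compared groups alone. The ± values beside CPM (counts scaled to a common library size, edgeR cpm) are standard deviations. A prior count of 2 was used for log2 CPM only. The common biological coefficient of variation was 16.0%.

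The contrasts numbered 25. In 12 of them bleomycin was set against saline of the same age and day. Another 7 tested whether the bleomycin effect differed between old and young lungs, on each of 6 days and as the mean over the days, and 2 tested the change of the effect from day 14 to day 56 within an age. The last 4 set old against young saline lungs as the mean over 6 days, old against young untreated lungs, and saline at day 14 against untreated lungs within each age. The groups, contrasts, settings and first alternatives were chosen before the data were examined. No paired analysis was possible because the labels give no replicate number shared between groups, and the labels hold no batch or date.

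Gene groups were 44 fixed lists of marker and pathway genes. Each list was tested with limma camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, with adjustment over the lists of a contrast. For each list the members measured, called higher and called lower were counted, with the members' p-values also adjusted over the list alone. A list score for a library is the mean log2 CPM of its members.

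Genes were named by a fixed rule. It took a panel of 26 genes in every contrast. It added the 8 largest rises and 6 largest falls among called genes with an average log2 CPM above 1 and no overlap between the libraries of the contrasted pair of groups, skipping predicted genes and antigen-receptor segments. It also took up to 4 members with the smallest p for each list, or 2 where the list was not called. A pair of genes that the rule names is not reported here. A named gene or list that was not called counts as same under an alternative unless it was called there.

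The alternatives were RLE scaling, no filter beyond 1 read, the DESeq2 Wald test with its own size factors and filtering, a fit on the groups of the contrast alone, and a fit without the libraries numbered apart from their group (old bleomycin day 28 libraries 127 and 131, day 42 library 142 and day 56 libraries 148, 149 and 150, and old saline day 56 libraries 143 to 147). In the leave-1-out fits library k was left out of every bleomycin group of an age, or of every saline and untreated group of an age. The lists were retested with the estimated correlation. Chosen after the values were seen were a fit without 5 libraries that stood apart (33, 89, 106, 118 and 125, more than 3 median absolute deviations out), a fit with a clock score as covariate, and a fit with a handling score as covariate. The clock score was the mean log2 CPM of Dbp, Nr1d1, Nr1d2, Per3, Tef and Ciart minus that of Arntl and Npas2.

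Chance was examined by relabelling the libraries of a contrast in up to 100 ways, the real one included, and counting the genes called. Group sizes were kept, but the splits were not balanced for the real labels, so some could lie close to the real one. Pairs of groups were tested with edgeR alone. The age differences and the changes from day 14 to day 56 used limma on residuals, and old against young saline used limma on log2 CPM. Single libraries were examined with Dixon's test on 26 genes in 6 groups.

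The procedure was checked on simulated data with 18396 genes of which 200 were changed. The changed genes were drawn from those with an average log2 CPM above 0, and each gene had the same dispersion in every group. For a contrast like young day 14 it recovered 58 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 63 of 66 changed 4-fold, with 10 false calls. For a contrast like the age difference at day 14 it recovered 35 of 67, 46 of 67 and 61 of 66, with 7 false calls. DESeq2 on the first set recovered 58, 58 and 65, with 12 false calls. The list test called the 1 list that was changed 1.5-fold, interstitial matrix, and 0 others. Genes were drawn independently there, so this check does not cover correlation between list members. In the real data that correlation was estimated at 0.75 for interstitial matrix at old day 14. A search for duplicated libraries over 316 pairs within groups gave a smallest chi-square per degree of freedom of 5.18 and a median of 16.8, where a duplicate by counting noise alone gives 1.

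Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.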

Results

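Messenger RNA was measured by poly-A sequencing in the lungs of male C57BL/6J mice, either young (8 to 12 weeks) or old (21 months). The mice had received bleomycin, a drug that injures the lung and leaves fibrosis, or saline, by instillation into the trachea, and lungs were taken 14, 21, 28, 35, 42 or 56 days later. The bleomycin dose was 0.7 mg/kg in young and 0.63 mg/kg in old mice, so age and dose changed together. The series set out to follow how fibrosis resolves and the lung is repaired, and how age alters this. Untreated lungs were taken at day 0 from 4 young and 5 old mice. From day 14 to day 56 the young saline groups held 5, 5, 5, 4, 5 and 5 lungs and the young bleomycin groups 5, 4, 5, 4, 5 and 4. The old saline groups held 6, 6, 5, 6, 6 and 11 lungs and the old bleomycin groups 6, 6, 5, 4, 5 and 6. Libraries held 14.9 to 31.02 M assigned reads, with a median of 21.1 M. Values below are log2 fold changes ± standard error from edgeR on 18396 genes. The standard error draws on the spread over all groups, not on that of the compared groups alone. Lungs are named by their replicate number within a group.

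A comparison of bleomycin with saline of the same age and day asked which transcripts the injured lung held at that day. In young lungs 7188 genes were called at day 14 (3696 higher, 3492 lower), 6678 at day 21, 5371 at day 28, 3626 at day 35, 1401 at day 42 and 2982 at day 56. In old lungs the counts were 10252 at day 14 (5383 higher, 4869 lower), 7815, 7295, 5443, 3610 and 2543 at the later days. Group sizes differed between ages, so these counts do not by themselves measure a difference between old and young. In a leave-1-out fit the replicate named was left out of every bleomycin group, or of every saline and untreated group, of its age. At day 35 such fits moved the count more than 1.5-fold, with 2361 genes in young lungs without bleomycin replicate 3 and 3552 or 3573 in old lungs without bleomycin replicate 1 or 3. At day 42 the young count was 751 without bleomycin replicate 4 and 925 without replicate 5, and the old count was 2203 without bleomycin replicate 1 and 2137 without replicate 5. A fit on the groups of the contrast alone gave 2106 genes at young day 42, and 4508, 1178 and 4201 at old days 28, 42 and 56, so the order of the last days in old lungs was not kept. Without the libraries numbered apart from their group old days 42 and 56 had 2130 and 1451.

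**Figure D1:**
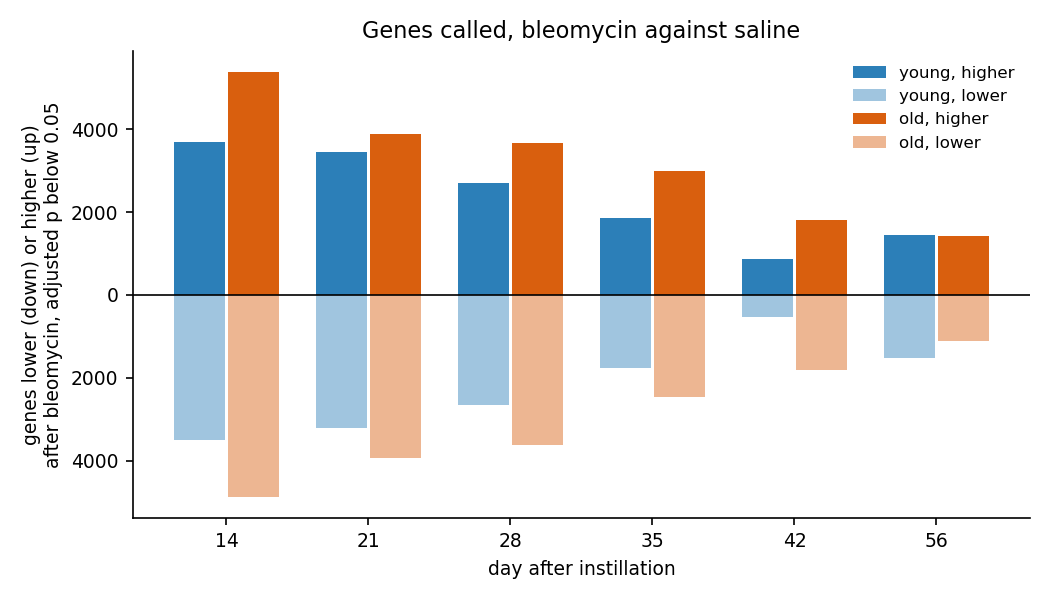
Number of genes called higher (bars up) or lower (bars down) after bleomycin than after saline (y axis) at each day after instillation (x axis), in young and old mice. The total fell from 7188 at day 14 to 2982 at day 56 in young lungs and from 10252 to 2543 in old lungs.

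In young lungs 14 days after bleomycin (n = 5 against 5), transcripts for scar matrix, for macrophages derived from monocytes and for cell division rose, while those of airway epithelium and vessels fell. The fibrillar collagen Col1a1 (ENSMUSG00000001506, GRCm38 chromosome 11, 94936224 to 94953042) rose from 495 ± 43.9 to 2080 ± 996 CPM (log2 2.07 ± 0.32), against 486 ± 52.9 CPM in 4 untreated lungs. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), which is laid down with it, rose by 1.68 ± 0.24. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), secreted by scar-associated macrophages, rose from 116.3 ± 21.9 to 2016 ± 788 CPM (4.12 ± 0.40). Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), the macrophage elastase, rose from 4.39 ± 0.689 to 142.6 ± 60.8 CPM (5.02 ± 0.53). Thbs4 (5.90 ± 0.65), a matrix glycoprotein, and Grem1 (4.91 ± 0.70), a BMP antagonist, were among the largest rises, and Fabp1 (−3.41 ± 0.45), a lipid carrier, was the largest fall named.

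By list, 23 of 25 interstitial matrix genes rose at young day 14 and none fell, among them the elastin gene Eln (2.82 ± 0.31) and tenascin Tnc (3.96 ± 0.46), with a median of 1.35 (camera adjusted p = 8.16e-16, and 0.172 with an estimated correlation). Of 20 genes of collagen processing and cross-linking 14 rose and 1 fell, including the cross-linking enzyme Lox (2.15 ± 0.29), with a median of 0.60 (adjusted p = 1.09e-08, and 0.172 with an estimated correlation). Of 18 basement membrane genes 15 rose, with Lama1 at 2.92 ± 0.35 (adjusted p = 1.39e-07, and 0.244 with an estimated correlation). Of 12 TGF-beta ligands and targets 9 rose and 2 fell (adjusted p = 6.47e-05, and 0.128 with an estimated correlation). The myofibroblast genes Acta2 (0.11 ± 0.19) and Postn (−0.02 ± 0.10) were not called, and of 12 contractile genes 2 rose and 2 fell, with a median of 0.12 and a mean of −0.01. Of 16 matrix-degrading proteases 15 rose and 1 fell, with the cathepsin Ctss at 2.58 ± 0.22 (adjusted p = 5.29e-14, and 0.00758 with an estimated correlation).

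Among immune lists at young day 14, 15 of 16 genes of monocyte-derived macrophages rose, with the lipid receptor Trem2 at 3.82 ± 0.28, Apoe at 2.04 ± 0.16 and C1qb at 2.89 ± 0.24 (median 1.87, adjusted p = 3.53e-21, and 0.00654 with an estimated correlation). Of 14 complement genes 13 rose (adjusted p = 7.28e-13, and 0.0483 with an estimated correlation), and of 21 chemokine genes 15 rose and 1 fell, with the monocyte attractant Ccl2 at 2.60 ± 0.37 (adjusted p = 2.77e-07, and 0.121 with an estimated correlation). Of 13 alveolar macrophage genes 2 rose and 5 fell, with a median of 0.26 and a mean of −0.44. B cell genes fell in 9 of 12 cases, with the receptor chain Cd79a at −1.48 ± 0.43 (adjusted p = 0.000754, and 0.499 with an estimated correlation). Cytotoxic and NK cell genes fell in 8 of 12, with perforin Prf1 at −1.44 ± 0.46 (adjusted p = 0.00344, and 0.471 with an estimated correlation). Of 18 T cell genes 3 rose and 1 fell, and the risen genes included the regulatory T cell factor Foxp3 (2.16 ± 0.38). Proliferation genes rose in 19 of 20 cases, with the mitotic kinase Cdk1 at 2.91 ± 0.39 (adjusted p = 1.25e-11, and 0.172 with an estimated correlation).

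In young lungs at day 14, 14 of 16 transitional alveolar genes rose, with the tight-junction gene Cldn4 at 2.78 ± 0.43, Sprr1a at 3.55 ± 0.45 and the keratin Krt8 at 0.60 ± 0.14 (median 0.89, adjusted p = 3.00e-10, and 0.0955 with an estimated correlation). The p53 targets rose in 11 of 15 cases, with the cell-cycle inhibitor Cdkn1a at 0.90 ± 0.15 (adjusted p = 4.73e-05, and 0.244 with an estimated correlation), and senescence genes in 12 of 14 with 1 fall, with Cdkn2a 2.47-fold higher (adjusted p = 3.19e-05, and 0.101 with an estimated correlation). Club cell genes fell in 10 of 10 cases, with the cytochrome Cyp2f2 at −1.32 ± 0.27 (median −1.13, adjusted p = 9.07e-07, and 0.223 with an estimated correlation), and ciliated genes in 11 of 12 (median −0.85, adjusted p = 6.47e-05, and 0.417 with an estimated correlation). Alveolar type 2 genes rose in 2 and fell in 4 of 12 cases, and type 1 genes rose in 3 and fell in 1 of 12; the surfactant gene Sftpc was not called (−0.31 ± 0.20). Endothelial genes fell in 14 of 18 cases, with the VEGF receptor Kdr at −0.84 ± 0.15 and the capillary gene Car4 at −0.55 ± 0.13 (adjusted p = 1.66e-05, and 0.244 with an estimated correlation). Cardiac muscle genes, which mark the muscle sleeves of the pulmonary veins, fell in 9 of 10 cases, with Ryr2 at −1.57 ± 0.36 (median −1.53, adjusted p = 0.000282, and 0.427 with an estimated correlation). Of 13 immediate early and handling genes 3 rose and 2 fell, and of 8 blood genes none was called.

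In old lungs at day 14 (n = 6 against 6) matrix, macrophage and proliferation genes rose and airway and vessel genes fell. Col1a1 rose from 382 ± 38.2 to 1691 ± 1160 CPM (2.14 ± 0.29), against 370 ± 16.5 CPM in 5 untreated lungs, and Col3a1 from 614 ± 79.8 to 2492 ± 1225 CPM (2.02 ± 0.22). Spp1 rose by 3.33 ± 0.35 to 2069 ± 603 CPM and Mmp12 by 3.72 ± 0.44 to 160 ± 64.9 CPM. Of 25 interstitial matrix genes 23 rose (median 1.24, adjusted p = 1.84e-10, and 0.443 with an estimated correlation). Of 16 proteases 14 rose and 1 fell (adjusted p = 7.16e-11, and 0.0295 with an estimated correlation), and of 16 genes of monocyte-derived macrophages 15 rose, with Trem2 at 3.25 ± 0.24 (adjusted p = 7.60e-16, and 0.0295 with an estimated correlation). Transitional alveolar genes rose in 14 of 16 cases (adjusted p = 1.91e-08, and 0.175 with an estimated correlation), and proliferation genes in 19 of 20 (adjusted p = 7.35e-08, and 0.443 with an estimated correlation). Club genes fell in 10 of 10 cases (adjusted p = 0.000204, and 0.487 with an estimated correlation), and endothelial genes in 12 of 18 (adjusted p = 0.000252, and 0.487 with an estimated correlation).

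Other lists at old day 14 included airway defence, where 8 of 11 genes fell, with the secreted protein Bpifa1 at −3.20 ± 0.86 (adjusted p = 0.0243, and 0.731 with an estimated correlation). Interferon response genes rose in 12 of 20 cases, with Isg15 at 1.58 ± 0.24 (adjusted p = 0.0128, and 0.733 with an estimated correlation), and oxidative phosphorylation genes in 14 of 18, with the cytochrome oxidase subunit Cox5a at 0.98 ± 0.14 (adjusted p = 0.000177, and 0.545 with an estimated correlation). Of 6 genes encoded in the mitochondrion 5 fell, with mt-Nd5 at −0.64 ± 0.13 (adjusted p = 0.0369, and 0.668 with an estimated correlation). Alveolar type 2 genes rose in 2 and fell in 3 of 12 cases, with a median of −0.03 and a mean of 0.05, and none of 12 B cell genes was called. Cardiac genes fell in 9 of 10 cases, with Myh6 at −2.23 ± 0.54 (adjusted p = 0.0044, and 0.668 with an estimated correlation). All 8 blood genes rose (median 3.13), but without bleomycin replicate 3 1 of them rose and 2 fell, with a median of −0.84. The blood score of that lung was 9.38. Of 9 skeletal muscle genes 6 rose, and 3 rose and 1 fell without replicate 3. Replicate 5, which stayed in that fit, had a skeletal muscle score of 2.23, against 2.39 in replicate 3.

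Whether old and young lungs responded alike was read across genes, which are not independent replicates. At day 14, 2978 genes rose in both ages against 1082 for independent calls, 2588 fell in both against 924, and 22 were called in opposite directions. The fold changes correlated across genes with Pearson r = 0.743 and Spearman rho = 0.726. From day 21 to day 56 Pearson r was 0.781, 0.776, 0.691, 0.559 and 0.726. At day 56, 880 genes rose in both ages against 113.3 for independent calls, 638 fell in both against 92.2, and none was called in opposite directions. With no filter on low counts Pearson r at day 14 was 0.354.

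**Figure D2:**
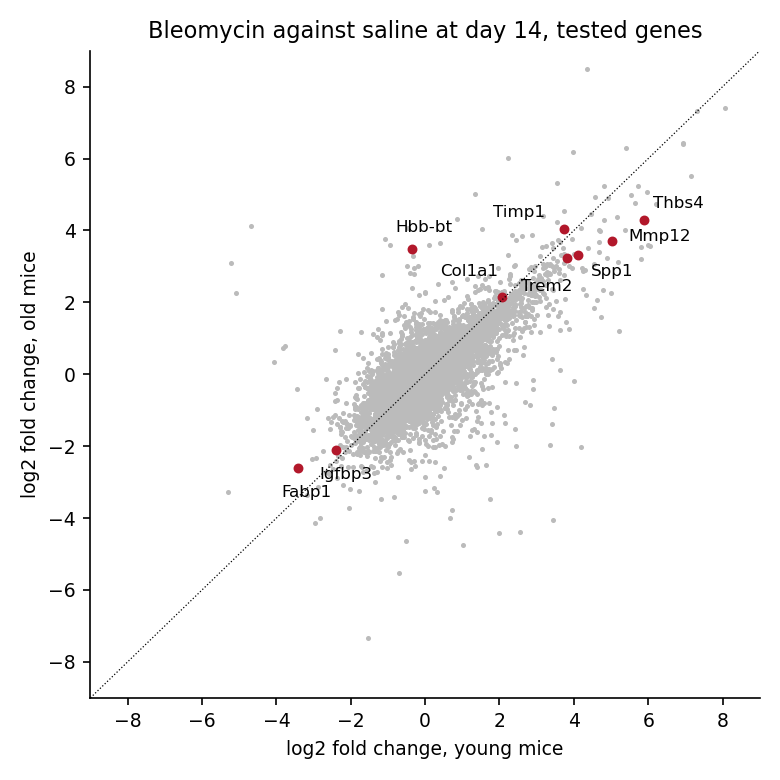
Log2 fold change of bleomycin against saline at day 14 in young mice (x axis) and old mice (y axis), with a point for each tested gene, some genes labelled in red, and a dotted line of equal change. The fold changes correlated with Pearson r = 0.743 across genes.

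Between day 21 and day 42 the number of matrix genes called fell in both ages. In young lungs 23, 20, 15 and 2 of 25 interstitial matrix genes rose at days 21, 28, 35 and 42, with medians of 1.20, 0.87, 0.66 and 0.14. In old lungs 24, 24, 21 and 18 rose, with medians of 1.64, 1.52, 1.17 and 0.72. The last of these was 13 genes with a median of 0.60 without replicate 6 of the old saline day-42 group, a lung with a matrix score of 6.08. Col1a1 in young lungs was 1.85 ± 0.32, 1.31 ± 0.31, 0.94 ± 0.34 and 0.13 ± 0.30 above saline at the 4 days, the last not called, and in old lungs 2.45 ± 0.29, 2.11 ± 0.32, 1.70 ± 0.31 and 1.11 ± 0.29. Its call at young day 35 was lost with no filter, with the clock covariate and in some leave-1-out fits, and at old day 42 with the groups alone. Adjusted p with an estimated correlation for interstitial matrix was between 0.0938 (old day 21) and 0.648 (young day 42) at these 8 comparisons. The age difference was tested directly at these 4 days and called none of the 25 genes on any of them. Its list medians were 0.22, 0.58, 0.26 and 0.50, higher in old lungs (adjusted p = 0.0143, 6.80e-09, 0.0228 and 5.82e-11, and 0.933, 0.841, 0.919 and 0.606 with an estimated correlation). The day-42 value includes replicate 6 of the old saline group, the lung with the low matrix score.

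**Figure D3:**
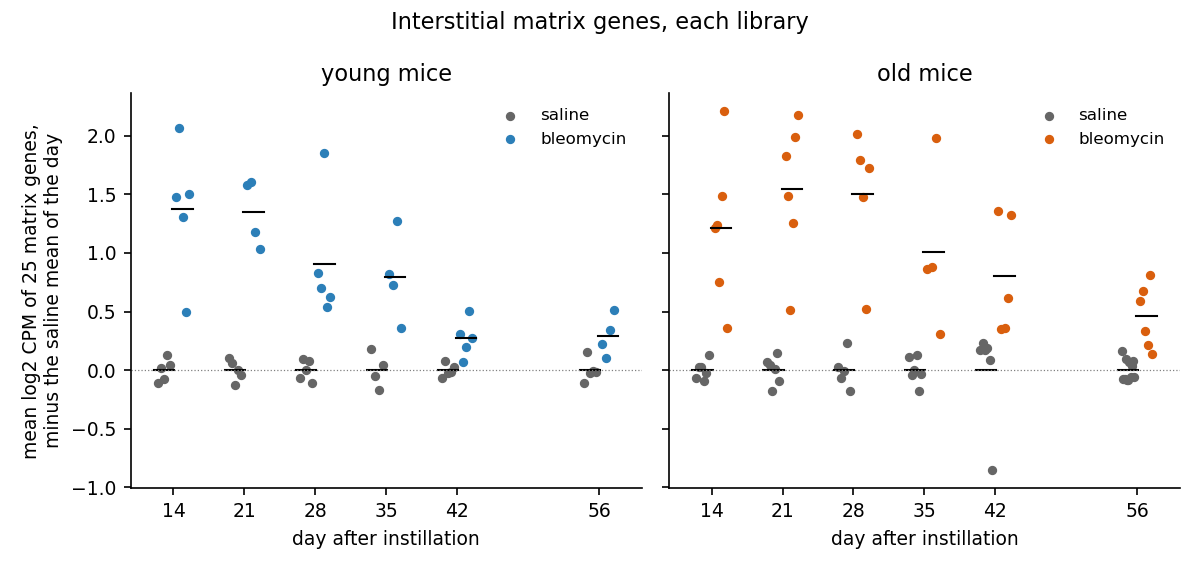
Interstitial matrix score of each lung (mean log2 CPM of 25 genes minus the saline mean of the same age and day, y axis) by day after instillation (x axis), with a point per saline or bleomycin lung and a line at each group mean. The bleomycin mean fell from 1.37 at day 14 to 0.29 at day 56 in young lungs and from 1.21 to 0.46 in old lungs, and 1 old saline lung at day 42 stood 0.85 below its group.

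Macrophage and plasma cell genes were counted over the same days, and their courses were not tested against that of the matrix genes. Of 16 genes of monocyte-derived macrophages, 15, 14, 14 and 12 rose in young lungs at days 21, 28, 35 and 42, and 13, 13, 13 and 14 in old lungs. Adjusted p for that list with an estimated correlation stayed between 0.0053 and 0.0541. Mmp12 was still 3.88 ± 0.52 above saline at young day 42. Plasma cell genes rose in 10, 6, 11 and 12 of 16 cases in young lungs, with medians of 1.66, 0.99, 2.22 and 2.41 and the joining chain gene Jchain at 3.64 ± 0.62 at day 42 (adjusted p = 2.46e-13, and 0.0276 with an estimated correlation). In old lungs 4, 6, 7 and 5 rose, with medians of 0.66, 1.03, 1.12 and 0.63. Proliferation genes rose in 17, 4, 4 and 0 of 20 cases in young lungs. In old lungs 19, 12, 13 and 0 rose at the 4 days, and 6 fell at day 42, where without saline replicate 6 only 1 rose and 1 fell. Interferon genes fell in 10 of 20 cases at old day 42, and without saline replicate 6 none fell and 2 rose. The lipofibroblast list fell in 9, 9, 8 and 10 of 12 cases in young lungs (at day 42 adjusted p = 1.03e-09, and 0.0159 with an estimated correlation). Large single changes were Grem1 at old day 21 (6.60 ± 0.67), Col24a1, a minor collagen, at old day 42 (4.14 ± 0.50), and the atrial hormone gene Nppa at old day 28 (−5.40 ± 1.05).

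**Figure D4:**
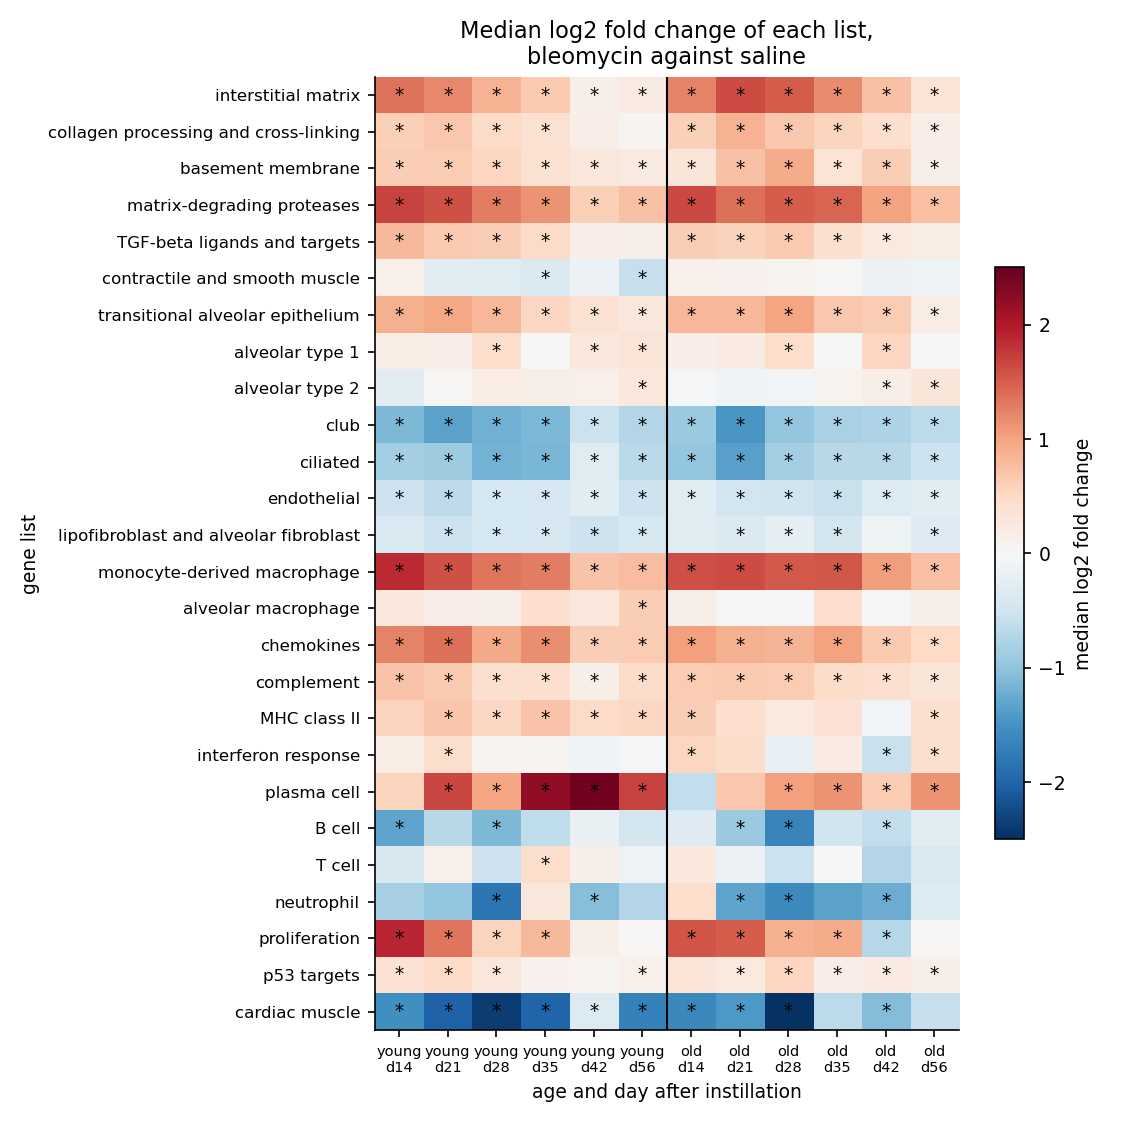
Median log2 fold change of bleomycin against saline (colour) of 26 gene lists (y axis) by age and day after instillation (x axis), with an asterisk where camera at the preset correlation gave an adjusted p under 0.05. The interstitial matrix median fell from 1.35 to 0.21 in young lungs and from 1.24 to 0.35 in old lungs between days 14 and 56.

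The comparisons at day 56 asked what was left at the last day measured. In young lungs (n = 4 against 5) the fibrillar collagens were no longer called while macrophage and plasma cell genes stayed high. Col1a1 was 535 ± 90.6 against 517 ± 110 CPM (0.05 ± 0.32) and Col3a1 was 0.36 ± 0.25, neither called. Mmp12 stood at 74.9 ± 31.3 against 4.15 ± 0.703 CPM (4.18 ± 0.53) and Spp1 at 925 ± 416 against 141.96 ± 9.93 CPM (2.70 ± 0.38). Ighg1 (ENSMUSG00000076614, chromosome 12, 113325240 to 113330523), an immunoglobulin heavy chain, rose by 5.06 ± 1.20 and Jchain by 3.42 ± 0.63; Ighg1 lost its call in a leave-1-out fit. Tnc (1.95 ± 0.44) was still high, as was Fn1 (1.09 ± 0.35), whose call was lost with the handling covariate and in some leave-1-out fits. The 2982 genes (1456 higher, 1526 lower) became 1832 without bleomycin replicate 3.

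By list at young day 56, 12 of 16 genes of monocyte-derived macrophages rose, with Trem2 at 2.56 ± 0.28 (adjusted p = 5.68e-15, and 0.0553 with an estimated correlation), and 9 of 16 plasma cell genes, or 13 adjusted over the list alone (adjusted p = 1.16e-08, and 0.137 with an estimated correlation). Of 16 proteases 7 rose and 1 fell, with Ctsk at 2.48 ± 0.31 (adjusted p = 2.76e-07, and 0.137 with an estimated correlation), and of 25 interstitial matrix genes 3 rose (adjusted p = 0.0193, and 0.812 with an estimated correlation). Mesothelial genes rose in 5 of 8 cases, with Bnc1 at 1.25 ± 0.26 (adjusted p = 2.29e-05, and 0.278 with an estimated correlation). Alveolar type 1 genes rose in 4 of 12, with the claudin Cldn18 at 0.77 ± 0.14 (adjusted p = 0.000289, and 0.412 with an estimated correlation), and lipid synthesis genes in 5 of 20, with Scd1 at 1.04 ± 0.20 (adjusted p = 0.00216, and 0.488 with an estimated correlation). Endothelial genes fell in 15 of 18 cases, with Tie1 at −0.49 ± 0.09 (adjusted p = 1.90e-11, and 0.137 with an estimated correlation), and contractile genes in 8 of 12, with Cnn1 at −1.26 ± 0.25 (adjusted p = 1.96e-05, and 0.278 with an estimated correlation). Club genes fell in 5 of 10 cases, or 10 adjusted over the list alone (adjusted p = 7.08e-05, and 0.408 with an estimated correlation). Cardiac genes fell in 9 of 10 (adjusted p = 1.67e-06, and 0.278 with an estimated correlation) and handling genes in 7 of 13, with Zfp36 at −0.89 ± 0.21 (adjusted p = 2.02e-06, and 0.278 with an estimated correlation). Zfp36 lost its call with the groups alone and with the handling covariate.

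In old lungs at day 56 (n = 6 against 11) collagen, macrophage and plasma cell genes were all still high. The age difference was tested directly at this day and called 0 genes, the collagens included. A collagen call in old and none in young lungs is therefore not by itself a difference between the ages. Col1a1 was 591 ± 142.7 against 373 ± 39.6 CPM (0.66 ± 0.24, adjusted p = 0.0478), a call that ended with no filter, with DESeq2, without the libraries numbered apart, with either covariate and in some leave-1-out fits. Col3a1 was 1159 ± 345 against 590 ± 64.6 CPM (0.97 ± 0.18). Mmp12 stood at 63.6 ± 25.1 against 15.6 ± 5.47 CPM (2.03 ± 0.35) and Spp1 at 904 ± 489 against 181 ± 23.1 CPM (2.32 ± 0.27). The adhesion gene Chl1 (3.09 ± 0.53) and Col24a1 (2.84 ± 0.38) were among the largest rises named, and Bex2 (−1.94 ± 0.29) was the largest fall named. The 2543 genes called became 1458 without bleomycin replicate 2 and 1650 without replicate 5.

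By list at old day 56, 11 of 25 interstitial matrix genes rose, with Col14a1 at 0.62 ± 0.10 (median 0.35, adjusted p = 6.06e-08, and 0.464 with an estimated correlation). Of 16 genes of monocyte-derived macrophages 13 rose, with Trem2 at 1.83 ± 0.19 (adjusted p = 1.09e-18, and 0.0156 with an estimated correlation), and of 16 proteases 10 rose and 1 fell, with Mmp19 at 1.54 ± 0.19 (adjusted p = 1.22e-10, and 0.0331 with an estimated correlation). Plasma cell genes rose in 12 of 16 cases, with Jchain at 2.14 ± 0.43 (adjusted p = 4.02e-08, and 0.229 with an estimated correlation). Alveolar type 2 genes rose in 7 of 12, with the surfactant protein Sftpd at 0.62 ± 0.11 (adjusted p = 1.40e-06, and 0.287 with an estimated correlation). Endothelial genes fell in 9 of 18, with Tek at −0.39 ± 0.09 (adjusted p = 1.09e-07, and 0.276 with an estimated correlation), and club genes in 6 of 10, with Cldn10 at −0.70 ± 0.17 (adjusted p = 9.53e-07, and 0.287 with an estimated correlation). No contractile, mesothelial or cardiac gene was called, while handling genes fell in 5 of 13 cases (adjusted p = 0.000661, and 0.471 with an estimated correlation).

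The contrast of day 56 with day 14 asked how far the bleomycin effect had receded within an age. It called 830 genes in young lungs (251 higher, 579 lower) and 4866 in old lungs (2000 higher, 2866 lower). The young count ran from 153 without replicate 2 of each bleomycin group to 1598 without replicate 4, and the old count from 2588 without replicate 6 of each bleomycin group to 6038 without replicate 3. Without the libraries numbered apart the old count was 1673. Col1a1 fell by 2.02 ± 0.45 in young and 1.48 ± 0.37 in old lungs, Timp1, an inhibitor of matrix proteases, by 2.74 ± 0.64 and 2.73 ± 0.53, and Lox by 2.42 ± 0.41 and 1.68 ± 0.34. In young lungs Col1a1 and Timp1 lost their calls without bleomycin replicate 2. Mmp12 fell in old lungs (−1.69 ± 0.55, a call lost without the libraries numbered apart) and was not called in young lungs (−0.85 ± 0.72), and Spp1 was called in neither (−1.41 ± 0.51 and −1.01 ± 0.43), though DESeq2 called it in both. Interstitial matrix genes fell in 14 of 25 cases in young lungs, or 21 adjusted over the list alone (adjusted p = 5.00e-18, and 0.125 with an estimated correlation), and in 17 in old lungs (adjusted p = 8.44e-07, and 0.589 with an estimated correlation). Proliferation genes fell in 13 of 20 cases in young lungs (adjusted p = 6.52e-19, and 0.109 with an estimated correlation) and in 17 in old lungs (adjusted p = 5.04e-10, and 0.323 with an estimated correlation). Plasma cell genes rose in 1 of 16 cases in young and in 12 in old lungs, where adjusted p = 1.16e-05, and 0.323 with an estimated correlation. In old lungs 7 of 8 blood genes fell, and without replicate 3 of the day-14 bleomycin group none fell and 2 rose.

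Of the 1027 genes at least 2-fold higher at young day 14, 378 (36.8%) were called higher at day 56, and their median fell from 1.63 to 0.65. Of the 992 such genes in old lungs 359 (36.2%) were, and their median fell from 1.49 to 0.49. Of the genes at least 2-fold lower at day 14, 235 of 660 (35.6%) in young and 256 of 933 (27.4%) in old lungs were called lower at day 56. Selection at day 14 by size favours a decline at other days.

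The age difference of the bleomycin effect, which also carries the dose difference, asked whether old lungs responded or recovered differently. By single days few genes were called, with 18 at day 14 (9 higher, 9 lower in old), 0 at day 21, 1 at day 28, 1 at day 35, 6 at day 42 and 0 at day 56. At day 21 edgeR had 1506 genes with unadjusted p under 0.05 and DESeq2 called 9, and at day 56 edgeR had 1056 and DESeq2 called 3. At day 14 the neural adhesion gene Opcml had a lower effect in old lungs (−1.73 ± 0.34) and the splicing factor Srsf3 a higher one (0.58 ± 0.12), but the 18 became 0 without replicate 3 of the young saline, 2 of the young bleomycin or 6 of the old bleomycin group, and 474 without replicate 3 of the old bleomycin group. With the groups alone none was called. The single genes of days 28 and 35, Dlk1 (−10.31 ± 2.02) and the seminal vesicle gene Svs5 (−15.22 ± 2.32), were chosen after their values were seen and each was high in 1 lung, with 180.2 CPM of Dlk1 in old saline replicate 5 and 16.4 CPM of Svs5 in young bleomycin replicate 1. In leave-1-out fits the count at day 28 ran from 0 to 74, the highest without young bleomycin replicate 3. At day 42, where the homeobox gene Meox2 differed by 0.92 ± 0.16, the count ran from 1 to 38, with 18 of 21 fits moved more than 1.5-fold and the highest without old saline replicate 4. It was 0 with the groups alone and 1 without the libraries that stand apart. In the simulated data the day-14 contrast recovered 46 of 67 genes that differed 2-fold. Those genes had an average log2 CPM above 0 and equal dispersion in every group, so recovery may be lower in the real lungs.

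As the mean over the 6 days the effect differed in 461 genes (226 higher in old, 235 lower), and in 295 without replicate 1 of every young saline group. The collagen response was larger in old lungs, by 0.62 ± 0.13 for Col3a1 (adjusted p = 0.00262) and 0.64 ± 0.17 for Col1a1 (adjusted p = 0.0241), with fibrillin Fbn2 at 1.20 ± 0.29. In 27 leave-1-out fits Col3a1 stayed between 0.52 and 0.69 and was called in each, and Col1a1 stayed between 0.50 and 0.74 and was called in 21. Col1a1 also lost its call with no filter (adjusted p = 0.0549). The Mmp12 response was smaller in old lungs (−1.54 ± 0.27, with −1.59 to −1.40 in the 27 fits), as was that of Ighg1 (−2.65 ± 0.63, with −3.06 to −2.04 and called in 26) and of Jchain (−1.54 ± 0.33). These are differences of the change against saline. Old saline lungs held more Mmp12, Ighg1 and Jchain than young saline lungs, and less Col1a1 and Col3a1. A smaller or larger response therefore does not mean a lower or higher level after bleomycin, which was not tested. The lipid transporter Mfsd2a (−1.07 ± 0.12) and the neutrophil receptor Cxcr1 (−1.36 ± 0.18) had the smallest adjusted p among the falls named. Tnc (0.39 ± 0.24), Fn1 (0.29 ± 0.19) and Spp1 (−0.08 ± 0.20) were not called.

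By list the mean age difference was positive for 5 of 25 interstitial matrix genes, or 14 adjusted over the list alone (median 0.24, adjusted p = 2.33e-09, and 0.733 with an estimated correlation). It was positive for 3 of 20 collagen processing genes, or 10 adjusted over the list alone (adjusted p = 4.38e-07, and 0.733 with an estimated correlation), and for 2 of 12 contractile genes, or 8 adjusted over the list alone (adjusted p = 4.27e-08, and 0.535 with an estimated correlation). It was negative for 6 of 16 plasma cell genes, or 9 adjusted over the list alone (median −0.67, adjusted p = 2.33e-09, and 0.348 with an estimated correlation), and for 1 of 10 MHC class II genes, or 6 adjusted over the list alone (adjusted p = 5.86e-05, and 0.733 with an estimated correlation). Of 16 genes of monocyte-derived macrophages 3 were lower in old lungs, among them Trem2 (−0.57 ± 0.15, lost in a leave-1-out fit), and the list was not called (adjusted p = 0.13). The cardiac list was called as higher with none of 10 genes called (adjusted p = 0.000499, and 0.757 with an estimated correlation).

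The comparison of old with young saline lungs (n = 40 against 29, mean over 6 days) asked how the background differed between the ages. It called 10500 genes (5620 higher, 4880 lower in old). Most lymphocyte and antigen-presentation genes were higher in old lungs and many matrix genes lower, though no list was called with an estimated correlation. The macrophage gene Cd5l (3.22 ± 0.47), the granzyme Gzmk (3.82 ± 0.36), the T cell attractant Cxcl9 (2.34 ± 0.31) and Jchain (2.33 ± 0.24) were higher. Ighg1 (2.89 ± 0.48) and Mmp12 (1.68 ± 0.20) were higher at baseline, as was Cdkn2a (1.09 ± 0.15), a marker of senescent cells. Col3a1 (−0.49 ± 0.09), Col1a1 (−0.31 ± 0.12, lost in a leave-1-out fit) and Postn (−0.53 ± 0.04) were lower. The heat-shock genes Hspa1a (−3.01 ± 0.22) and Hspa1b (−3.30 ± 0.27) were the largest falls named, and the clock output Dbp was higher (1.81 ± 0.16) while Arntl, its activator, was lower (−0.59 ± 0.05). With the clock score as covariate 8281 genes were called, 8020 of them among the 10500.

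By list in saline lungs, 17 of 18 T cell genes were higher in old mice, with Cd8a at 1.79 ± 0.20 (median 1.28, adjusted p = 1.86e-09, and 0.469 with an estimated correlation), as were all 10 MHC class II genes, with H2-DMb1 at 0.68 ± 0.05 (adjusted p = 5.67e-09, and 0.469 with an estimated correlation). Of 16 plasma cell genes 14 were higher and 1 lower (adjusted p = 1.56e-06, and 0.469 with an estimated correlation). All 12 neutrophil genes were higher (adjusted p = 0.000518, and 0.671 with an estimated correlation), and 11 of 12 B cell genes (adjusted p = 0.00778, and 0.845 with an estimated correlation). Of 16 genes of monocyte-derived macrophages 12 were higher and 1 lower (adjusted p = 4.37e-05, and 0.671 with an estimated correlation). Of 18 basement membrane genes 14 were lower, with Nid2 at −0.47 ± 0.06 (adjusted p = 0.0009, and 0.845 with an estimated correlation), and of 25 interstitial matrix genes 13 were lower and 1 higher (adjusted p = 0.0143, and 0.901 with an estimated correlation). Of 12 alveolar type 1 genes 8 were lower and 1 higher (adjusted p = 0.0156, and 0.845 with an estimated correlation), and of 18 endothelial genes 11 were lower and 2 higher (adjusted p = 0.00971, and 0.845 with an estimated correlation). Handling genes had a median of 0.19 and a mean of −0.35, with 3 higher and 3 lower of 13, and clock genes a median of 0.05 and a mean of 0.09 with the list test pointing down, with 6 higher and 6 lower of 15.

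**Figure D5:**
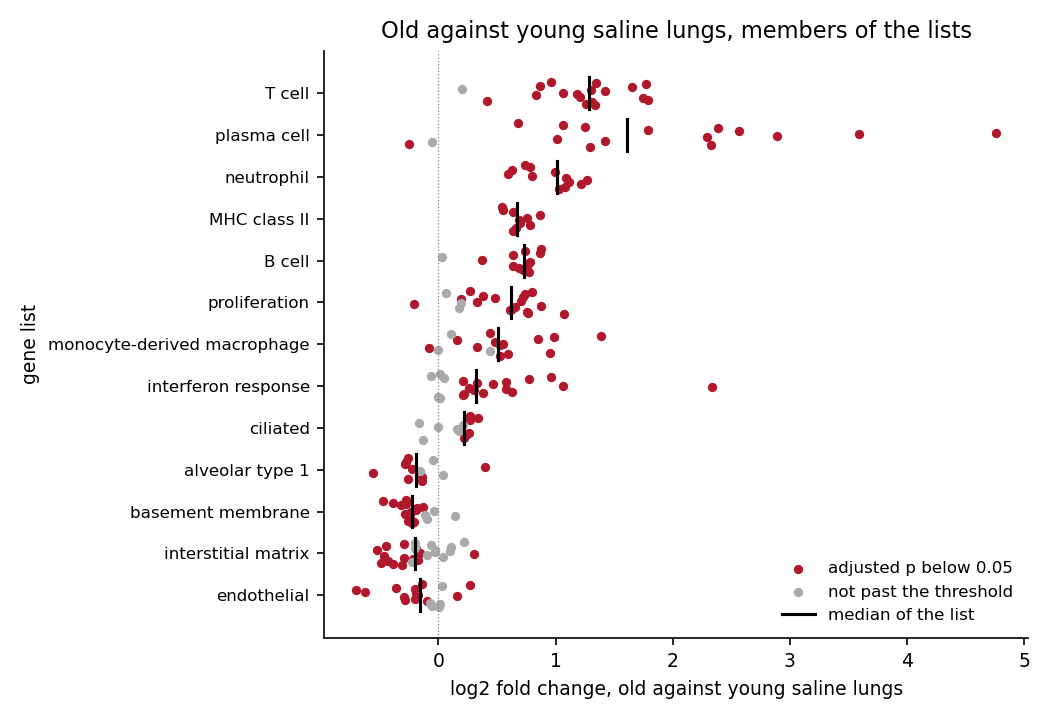
Log2 fold change of old against young saline lungs (x axis) for each member of 13 gene lists (y axis), red where the gene was called, with a line at each list's median. The median was 1.61 for plasma cell and 1.28 for T cell genes, and −0.23 for basement membrane genes.

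Old and young untreated lungs (n = 5 against 4) differed in 1021 genes (734 higher, 287 lower in old). Cd8a (2.87 ± 0.56) and the chemokine receptor Cxcr3 (2.57 ± 0.46) were higher in old lungs, and Phex (−1.78 ± 0.23), a peptidase gene, was lower. Of 18 T cell genes 14 were higher (median 1.76, adjusted p = 8.10e-11, and 0.505 with an estimated correlation), but only 1 was without old replicate 2, a lung with 142.9 CPM of Cd8a. Mmp12 was lower in old lungs (−3.37 ± 0.50) only through young replicate 3, a lung with 349 CPM of it, without which the sign turned (0.52). The gene count was 282 without young replicate 4, 583 without old replicate 4, 634 without old replicate 2 and 91 in a fit on these groups alone, where Cd8a and Cxcr3 were not called.

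Saline lungs at day 14 were set against untreated lungs to measure the effect of instillation, which day could not be separated from. In young lungs (n = 5 against 4) 0.712% of the genes tested were called, 2 of them higher and the rest lower, and none was called in a fit on these groups alone. The value of Mmp12 (−4.39 ± 0.53) rested on untreated replicate 3, at 349 CPM against 5.55 to 6.55 in the other 3 untreated lungs, and without replicate 3 of both groups its call was lost and 17 genes were called. Mesothelial genes fell in 6 of 8 cases (adjusted p = 2.28e-20, and 0.00294 with an estimated correlation), complement genes in 4 of 14 (adjusted p = 1.51e-18, and 0.00816 with an estimated correlation) and chemokine genes in 3 of 21 (adjusted p = 2.20e-13, and 0.0116 with an estimated correlation). Without those lungs 2, 1 and 0 fell. In old lungs (n = 6 against 5) 31 genes were called (11 higher, 20 lower), and 10 were called without replicate 2 of both groups, 8 with the clock covariate and 1, not among the 31, with these groups alone. Clock genes led the 31, with Dbp at 2.01 ± 0.38, from 11.3 ± 3.76 to 45.4 ± 20.3 CPM, and Arntl at −0.67 ± 0.13, neither called with these groups alone. Of 15 clock genes 5 rose and 3 fell (adjusted p = 2.66e-05, and 0.0505 with an estimated correlation). No gene of the matrix, macrophage or alveolar lists was called in old lungs.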

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

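The tests of relabelled libraries, of the cardiac genes and of an untreated lung were chosen only after the results were seen, while the predictions for the clock and handling covariates were written before those fits were run.

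Old and young saline lungs differed in 10500 genes, and clock genes were among them, so the time of day at which the lungs were taken, or the handling before lysis, might account for the difference. With the clock score as covariate 8281 genes were called and with the handling score 9838, of which 8020 and 9643 were among the 10500. This counts against the time of day, as far as the clock score measures it, as the sole cause. Handling genes moved in both directions between the ages, so their mean score could miss a difference in handling. The fit with that score therefore cannot decide on handling, which stays open. The mean clock score lay between −0.10 and 0.41 in young saline groups and between 0.99 and 1.83 in old saline groups. Age and clock score were thus partly confounded, and the part they share could not be divided. The score was also higher after bleomycin than after saline at every age and day. It was 1.56 against −0.10 at young day 21 and 1.51 against 1.08 at old day 42. The bleomycin comparisons thus share the confound, and whether the score measured time of day or injury was not tested. Relabelling ages within days called at most 1673 genes in the other splits against 10995 for the real one (1 of 100 splits reached it), so chance is unlikely to explain the count. Library numbers ran from 2 to 72 in young and from 73 to 150 in old mice. Whether they follow the order of processing was not given, but such an order could not be told apart from age. Neither relabelling nor a covariate addresses this. Cage, cohort and delivery date were not given and remain open.

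The cardiac muscle list was lower after bleomycin than after saline by 0.47 to 2.76 in 12 comparisons, the least at old day 56, where no member was called. If added cells had merely diluted the tissue, the cardiac and endothelial lists would fall alike, but the cardiac list fell by 1.18 ± 0.205 more as a mean over 12 comparisons (−1.65 against −0.474; difference −1.18). At old days 35 and 56 the difference was only −0.22 and −0.17, so dilution stays open there. If heart or vein tissue had been trimmed differently between the arms regardless of injury, the cardiac score would not follow injury within groups, but it fell as the matrix score rose (Pearson r = −0.488, permutation p = 7.0e-05; Spearman rho = −0.494, permutation p = 7.0e-05; 59 bleomycin lungs, deviations from group means, 1 relation tested, 2-sided). Without the 2 lungs farthest from the median r was −0.459. Differences in the part of the lung that was sampled could relate the 2 scores as well, and were not tested. A loss of cardiomyocytes from the veins or a lower expression in them may remain, and so may trimming that depends on how stiff or stuck the lung was, since neither was tested.

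Replicate 3 of the young untreated group held Mmp12 at 349 CPM, where the other 3 young untreated lungs had 5.55 to 6.55. A wrong label or an admixture of a bleomycin library could give such values. Of 60 genes high in it, leaving out immunoglobulins, 51 (85%) lay above every one of 27 young bleomycin libraries. A bleomycin library treated the same way reached at most 53.8% (replicate 2 at day 14). The 51 included the keratin Krt5 (59.5 CPM against at most 6.61 after bleomycin) and the fat gene Adipoq (26.7 against 14.2). Mmp12 also lay above (349 against 240.6), while Gpnmb did not (219.4 against 548.9). Other tissue taken with a mislabelled or admixed bleomycin lung could raise the share too, so the share does not decide on either. Lungs earlier than day 14 were not measured, so an acute injury or an infection in that mouse remains open. Keratins of basal cells and fat genes were among the 60, so airway or fat tissue taken with that lung remains open as well; none of these was tested.

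Dixon's test at 5% singled out a lung in 11 of 156 tests (26 genes in 6 groups), where 7.8 are due to chance. In replicate 3 of the young untreated group it did so for Spp1 (ratio 0.933), Mmp12 (0.961), Arg1 (0.856), Gpnmb (0.954) and Cldn4 (0.870), each highest. Spp1 was lowest in replicate 4 of the young bleomycin day-14 group (0.850), and Arg1 lowest in replicate 1 of the young bleomycin day-56 group (0.830). Gpnmb was lowest in replicate 2 of the old untreated group (0.752), and Sftpc lowest in replicate 6 of the old bleomycin day-56 group (0.714). In the old bleomycin day-14 group Cthrc1 was highest in replicate 5 (0.719) and Car4 highest in replicate 6 (0.730).

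The age difference of the bleomycin effect was called in 18 genes at day 14, 1 at day 28, 1 at day 35, 6 at day 42 and 461 as the mean over days. As that mean, Col1a1 differed by 0.64 ± 0.17, Col3a1 by 0.62 ± 0.13, Mmp12 by −1.54 ± 0.27 and Ighg1 by −2.65 ± 0.63. The change from day 14 to day 56 was called in 830 genes in young and 4866 in old lungs.

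The real split of a bleomycin comparison called the most genes of all splits in 11 of 12, where chance is unlikely to explain the count. The real and highest other counts in young lungs were 7631 and 2880 at day 14, 7296 and 2992 at day 21, 4146 and 0 at day 28, 3205 and 0 at day 35 (35 splits) and 3390 and 1031 at day 56. At young day 42 the real split called 2106 and the highest other 5.60% of that. In old lungs they were 7067 and 3947 at day 14, 7330 and 3326 at day 21, 4508 and 2167 at day 28, 4262 and 0 at day 35, and 4201 and 2 at day 56. At old day 42 the real split called 1178 and 1 other split of 100 called 1888, so 2 splits reached the real count. Chance was not excluded there, and the split that called more was not explained.

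For the age differences the real split of 100 called 1 gene at day 14 (highest other 1), 11 at day 21 (188) and 3 at day 56 (162), with 2 splits reaching it each time. At days 21 and 56 the highest other split called many times the real count, and what set that split apart was not explained. In the edgeR fit the clock and handling covariates gave 0 and 4 genes at day 21 and 0 with each at day 56, but the splits were not rerun with them, so a structure of the samples other than age stays open. At days 28, 35 and 42 the real split called 0 genes, a count that all 100 splits reach (highest 523, 9 and 10), so relabelling says nothing about the genes that edgeR called there. The mean over days called 389 (highest other 167), the young change 686 (9) and the old change 3827 (32), with 1 split of 100 reaching the count, so chance is unlikely to explain these counts. Untreated lungs of the 2 ages gave 91 against 3. Young saline against untreated lungs gave 0 against 2, which all splits reach, so it says nothing about the genes called with all libraries. Old saline against untreated lungs gave 1 against 2, with 2 splits reaching it.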

How the results depend on the processing

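The fits without the libraries that stand apart and with the clock or handling score were chosen only after the results were seen. Of 1594 named-gene results, 1580 were the same with RLE, 1575 with DESeq2, 1541 with the handling score, 1523 with the clock score and 1516 with no filter. With only the groups of the contrast 1422 were the same, 65 stronger and 94 weaker, and the rest had no value. The number of genes called moved more than 1.5-fold in 1 of 25 contrasts with RLE, 7 with no filter, 6 with DESeq2, 13 with only the groups, 2 with each covariate, 5 of 9 without the libraries numbered apart and 3 of 12 without those that stand apart. No replicate block was run, because the labels give no replicate number shared between groups. Unless a reason is given, the cause was not tested.

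Fitting only the groups of a contrast estimates dispersion from fewer samples, and from the spread of those groups alone. Counts moved both ways, up from 1401 at young day 42 and from 2543 at old day 56, and down from 3610 at old day 42. Fewer samples alone therefore do not account for the moves, and their cause was not tested. It gave 2106 genes at young day 42, 4508 at old day 28, 1178 at old day 42 and 4201 at old day 56. For the age difference it gave 0 at day 14, 32 at day 21, 0 at day 28, 0 at day 35, 0 at day 42 and 3 at day 56. It gave 91 for untreated lungs, 0 for young saline against untreated and 1 for old saline against untreated.

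Without the libraries numbered apart, which leaves fewer samples, old day 42 had 2130 genes, old day 56 had 1451 and the old change 1673. The age difference had 2 at day 42 and 6 at day 28, the last a rise, whose cause was not tested. With no filter, which tests more genes, the age difference had 3 at day 14, 0 at day 28, 1 at day 42 and 279 as the mean, the young change 431, untreated lungs 644 and old saline against untreated 16. DESeq2 gave age differences of 70 genes at day 14, 9 at day 21, 8 at day 28, 0 at day 35, 26 at day 42 and 3 at day 56. RLE gave 2 at day 42. Without the libraries that stand apart the age difference had 1 gene at day 14, 97 at day 28 and 1 at day 42. The clock score gave 2 at day 28 and 8 for old saline against untreated, and the handling score gave 4 at day 21 and 0 at day 28.

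Pearson r between ages was 0.354, 0.366, 0.327, 0.271, 0.178 and 0.251 by day with no filter, and 0.834, 0.861, 0.861, 0.797, 0.663 and 0.805 with only the groups. With an estimated correlation 3 of 20 lists stayed called at young day 14, 2 of 20 at old day 14, 0 of 23 at young day 56, 2 of 19 at old day 56 and 0 of 17 for old against young saline.

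Leaving out 1 library per group moved 99 of 346 counts more than 1.5-fold. The lowest and highest counts in young lungs were 5965 and 7865 at day 14, 5765 and 6201 at day 21, 3869 and 5831 at day 28, 2361 and 4236 at day 35, 751 and 1688 at day 42, and 1832 and 2984 at day 56. In old lungs they were 9187 and 10608, 7063 and 8270, 6415 and 7981, 3552 and 6479, 2137 and 3689, and 1458 and 3209. The age difference ran from 0 to 474 at day 14, 0 to 6 at day 21, 0 to 74 at day 28, 1 to 4 at day 35, 1 to 38 at day 42, 0 to 1 at day 56 and 295 to 658 as the mean. The young change ran from 153 to 1598, the old change from 2588 to 6038, old against young saline from 9730 to 10502, untreated lungs from 282 to 1014, and saline against untreated lungs from 17 to 1.3e2 in young and from 10 to 65 in old mice.

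Directions turned for few named genes. In leave-1-out fits of the old change Alas2 ran from −4.75 to 0.72, Hba-a1 from −4.23 to 0.32, Hba-a2 from −4.15 to 0.15 and Hbb-bt from −4.92 to 0.16. These turned without replicate 3 of the old bleomycin groups. In untreated lungs Arg1 ran from −4.57 to 0.034, Gpnmb from −1.24 to 0.18 and Mmp12 from −3.77 to 0.52, and these turned without replicate 3 of the young group. Npas2 in old saline against untreated lungs was 0.13 with the clock score, which is computed in part from it. Depth, at 14.9 M reads or more per library, limits genes under the filter.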

Other observations

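The genes described here for single lungs were chosen only after their values were seen. Replicate 3 of the young untreated group, described for Mmp12, was also high in macrophage, eosinophil, basal cell and fat genes, a grouping that no list test backs. Its values were 99.2 CPM for Arg1 against 0.858 to 1.77 in the other 3 young untreated lungs, 894 for Retnla against 34.4 to 82.4, and 3813 for the chitinase-like Chil3 against 431 to 597. The eotaxin gene Ccl11 stood at 23.1 against 1.62 to 3.63, and the eosinophil ribonuclease Rnase2a at 29.6 against 0. The keratins Krt5, Krt15 and Krt14 stood at 59.5, 66.99 and 35.6 CPM against at most 0.812, 1.31 and 0.908, and the fat genes Adipoq, Plin1 and Car3 at 26.7, 39.2 and 237 against at most 6.17, 9.52 and 54.4.

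Clock genes were set differently by group. The mean clock score was 0.23 in young and 0.20 in old untreated lungs, from 0.60 to 1.62 in young bleomycin groups and from 1.51 to 2.72 in old bleomycin groups. Each bleomycin group lay above the saline group of its age and day. The score of old saline lungs at day 14 was 1.83. Dbp stood at 9.68 ± 1.68 CPM (n = 4) in young untreated and 13.6 ± 11.3 (n = 5) in young saline day-14 lungs. No time of day was given in the sources used here.

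Some old lungs were rich in T cell transcripts. Replicate 2 of the untreated group held 142.9 CPM of Cd8a against 7.92 to 18.4 in the other 4 old untreated lungs. Replicate 6 of the saline group at day 42 held 105.3 CPM of Cd8a and 33.7 of Gzmk, and its matrix score was 6.08. The T cell scores of these lungs were 4.67 and 4.43. Other old lungs had like scores, with 4.56 in saline day-56 replicate 6, 4.10 in saline day-42 replicate 3 and 4.05 in bleomycin day-42 replicate 2.

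A few lungs carried transcripts of other tissues. Hbb-bs was at 6711 CPM in replicate 3 of the old bleomycin day-14 group, whose blood score of 9.38 compared with 0.45 to 3.79 in the others of that group. The skeletal muscle score was 2.39 in that lung, 2.23 in replicate 5 of the same group and 3.06 in replicate 1 of the young untreated group. Svs5, a seminal vesicle gene, stood at 16.4 CPM in replicate 1 of the young bleomycin day-35 group, and Dlk1 at 180.2 CPM in replicate 5 of the old saline day-28 group.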
